A study of Homo sapiens with 2 samples.

How the data were processed

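The samples were 1 YTHDF3 RIP library and 1 input library from untreated KYSE30 cells grown with 10% serum, grouped by their titles. Per the labels' protocols, cells were lysed and RNA-protein complexes immunoprecipitated, RNA of both samples was fragmented and copied with random hexamers, molecular identifiers were added with the adapters so that duplicates could be removed, and libraries of about 300 bases were sequenced as pairs of 150-base reads. Coordinates are hg38, per the submitters' processing notes. The aligner, peak caller, gene annotation, thresholds, strand setting and use of the molecular identifiers in the files are not given in the sources used here. Random hexamers copy RNA with or without a poly(A) tail, so unspliced and noncoding RNA can also receive reads.

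The values come from 1 peak list that the authors made from the RIP library against the input library. Per the file headers, each peak has a fold enrichment, a ratio of RIP over input as the authors' caller scaled it. The deposited p-value and adjusted p-value of each peak are on a linear scale and compare the reads of these 2 libraries, not conditions. A further column repeats the p-value rounded. Every p-value was at most 0.049, and adjusted p-values reached 0.335, so the list was not restricted to adjusted p-values under 0.05; 147 p-values were listed as 0. No counts per peak and no library totals were used here, so depth is unknown and no error of a fold enrichment could be computed. A fold over a low input is imprecise and cannot be told from a precise one by its size. For most named genes the fold enrichment is printed without its p. The best fold enrichment of a gene need not lie in its peak with the smallest p.

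Starts were taken as counted from 0 and ends from 1, because 786 starts lay 1 below the start of their gene in the reference and 68 equalled it, while 702 ends equalled the gene's end; starts are printed counted from 1. Gene names of the file were matched to a RefSeq table of GRCh38.p14, the same build, on the same chromosome and within 100000 bases. This tolerance was widened from strict overlap after unmatched names were seen. Of the peaks, 16536 matched through the symbol and 749 through an older symbol. Another 23 peaks carried 14 names that a spreadsheet had turned into dates, and their coordinates gave 14 genes. For 1158 peaks under 963 names no match was found; these keep the file's name. The 9275 names gave 9268 genes.

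The comparisons were fixed before the data were examined, with 24 gene lists of 1060 genes in all drawn from general knowledge, 4 of them mitotic and also joined into 1. For each list the number of genes with a peak was counted, with an exact (Clopper-Pearson) 95% interval that covers counting error only and treats genes as independent. The share was placed as a percentile among 10000 random lists of the same size from the 19974 protein-coding genes, matched over 20 bins of gene length. The median over genes of the best peak's fold enrichment was placed likewise among genes with a peak. The plan was to match on transcript length. Gene length here is genomic length instead, since transcript lengths were not used, so no percentile is controlled for transcript length. Percentiles describe these libraries, are not p-values, and are left out for lists with under 80% of their genes in the background. Calling a list outside the middle 95% (percentiles 2.5 and 97.5) was chosen after the data were seen. Peaks were also simulated over the 19974 genes. Of 200 lists of 60 genes raised by 25 percentage points, 99.5% fell outside for the share, and of 200 unchanged lists 6.0%. For the median, simulated fold enrichments without steps were raised instead, with a value for every gene, and 98.5% and 3.0% fell outside. These values do not cover lists with few genes with a peak, or fold enrichments that repeat the same values. Apart from the raised lists, the simulated chance of a peak depended on gene length alone. The values therefore do not cover gene lists that differ from the background in expression, and are not a rate of false calls for the real lists.

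The genes named are the 10 with the largest best fold enrichment, the 5 with the most peaks, the 10 leading genes of the joined mitosis lists and the 2 leading genes of each other list by fold enrichment, and YTHDF1, YTHDF2, YTHDF3, METTL3 and METTL14. Genes of equal fold enrichment were ordered by p, and genes with equally many peaks by symbol, so the last gene named in a group can share its value with genes not named. A few genes that this rule names are not reported here. The positions of short peaks along genes, the overlap of peaks on opposite strands, the spacing of fold enrichments and the gene families were examined after the data were seen. Alternatives were stricter thresholds, other matching of random lists, other summaries per gene, other rules for peaks and names, and each mitosis list left out. The planned shares by transcript part, positions around stop codons and m6A motif counts need a genome sequence and transcript models and were not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.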

Results

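An antibody was used to recover RNA with YTHDF3, a cytoplasmic reader of the RNA modification N6-methyladenosine (m6A). The cells were KYSE30, an established line of human esophageal squamous cell carcinoma. The recovered RNA was sequenced beside RNA from the same lysate taken before the immunoprecipitation. The cells received no treatment. The data are 1 YTHDF3 RNA immunoprecipitation (RIP) library and 1 input library, and the authors' list of regions enriched in the first over the second. With 1 library of each kind there is no replicate error, and every comparison describes these 2 libraries only. Neither is from a control antibody or from cells without YTHDF3, so binding by YTHDF3 was not separated from nonspecific recovery. Read totals per library were not analysed here, so the depth behind a peak is unknown. The fold enrichment, p and adjusted p of each peak are the authors' own values, and coordinates are hg38.

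The series addresses which transcripts YTHDF3 binds in these cells. Peaks were listed for 9268 genes, among them 7994 protein-coding genes, or 40.0% of the 19974 protein-coding genes on chromosomes 1 to 22 and X. A further 280 genes with a peak were long noncoding RNA genes. The 3 YTHDF readers were all on the list: YTHDF1 with a fold enrichment of 16.7, YTHDF2 with 10.7 and YTHDF3 itself with 10.7 for its best peak. The largest fold enrichment of all belonged to POGK, a gene for a protein with a KRAB domain, at 87.8 over a region of chromosome 1 from 166839447 to 166854607.

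The list held 18466 peaks, with a median fold enrichment of 5.02 and quartiles of 2.76 and 8.78. A single peak was listed for 4559 genes, and 510 genes had 5 or more. Large genes led by number of peaks: DST, which codes for a cytoskeletal linker, had 16, SYNE2 of the nuclear envelope had 15, the ribosome assembly factor MDN1 had 14, the cytoskeletal linker MACF1 had 13 and the histone methyltransferase KMT2D had 12. Their median fold enrichments over those peaks lay between 2.51 in MDN1 and 6.27 in KMT2D. Protein-coding genes of chromosome 16 had a peak most often, at 48.9%, and those of the X chromosome least often, at 25.8%.

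Peaks were listed as genomic regions that could span introns, with a median span of 3322.5 bases, and 715 exceeded 100000 bases. Which exon, intron or untranslated region a peak covers was not analysed here. Every listed p was at most 0.049, whereas 4734 peaks (25.6%) had an adjusted p of 0.05 or more, and 7739 genes had at least 1 peak with an adjusted p under 0.05. For 3347 peaks (18.1%), the region overlapped a peak listed for another gene.

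After POGK, the best fold enrichments belonged to QTRT2, a subunit of the enzyme that places queuine in transfer RNA (82.8, chromosome 3 from 114087259 to 114088273), and to the membrane ubiquitin ligase gene MARCHF9 (79.0, chromosome 12 from 57755098 to 57759841). FAM20B, a xylose kinase of proteoglycan synthesis, followed at 77.8, and the cell cycle transcription factor E2F2 at 66.5 on chromosome 1 from 23506430 to 23531220. CDCP1, a transmembrane glycoprotein, reached 57.7, and NOG, which codes for the secreted antagonist of bone morphogenetic proteins noggin, 56.5. ERN1, a sensor of unfolded proteins in the endoplasmic reticulum, reached 55.2, EXD3 54.6 and ANKRD33B 51.4. The adjusted p of these 10 peaks ranged from 0 as listed for POGK to 6.3e-19 for ERN1. Of these 10 fold enrichments, 9 were whole multiples of 1.2546, a spacing that 50.3% of all peaks share, within the rounding of the list. The smallest listed p, 0, was shared by 144 genes, of which POGK was 1; the other 9 genes had larger p.

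The title of the series names mitosis-associated genes as its subject. Of 175 genes in 4 lists of mitotic genes, 117 had a peak, or 66.9% (59.4 to 73.8, exact 95% interval). The share in random lists of protein-coding genes matched on gene length had a median of 44.6%, and none of 10000 such lists was as high (percentile 100). Spindle and cytokinesis genes had a peak most often, with 42 of 53 genes (79.2%, percentile 100). Kinetochore and checkpoint genes followed with 31 of 48 (64.6%, percentile 99.9), and mitotic kinases, cyclins and their regulators with 19 of 30 (63.3%, percentile 98.5). For cohesin, condensin and the anaphase-promoting complex, 25 of 44 genes had a peak (56.8%), which lay within the middle 95% of random lists at percentile 95.4, and above it with an adjusted p under 0.05 (98.4) and with random lists not matched on length (98.7).

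The mitotic gene with the largest fold enrichment was HASPIN, the kinase of histone H3 at centromeres, at 33.9 on chromosome 17 from 3723903 to 3726699. KNL1, the kinetochore scaffold that recruits checkpoint proteins, followed at 25.1, on chromosome 15 from 40662458 to 40663504. The kinesin genes KIF18A, KIF18B and KIF14 had best fold enrichments of 21.3, 18.8 and 17.6, and the cohesin subunit gene SMC1A 17.6. The kinetochore genes CENPP and DSN1 stood at 17.6 and 15.1, and the centrosome and spindle genes NDE1 and TACC1 at 15.1 each. The CENPP region overlapped a peak of another gene. In the gene's peak with the smallest p, the fold enrichment was 6.23 for KNL1, 3.11 for KIF14 and 3.76 for CENPP. It was 8.78 for TACC1 and 11.3 for DSN1. For HASPIN, KIF18A, KIF18B, SMC1A and NDE1, that peak was also the one with the largest fold enrichment. Many of the best known mitotic regulators were without a listed peak, among them CDK1, CCNB1, CCNB2, CCNA2, AURKB, BUB1, TTK, CDC20, MAD2L1 and KIF11, while PLK1 and AURKA had best fold enrichments of 1.69 and 2.33. These 12 genes were singled out after their values were seen.

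Over the 117 mitotic genes with a peak, the median of the best fold enrichment was 5.02, at percentile 0. Random lists of genes with a peak had a median of 7.53 (6.27 to 8.78, middle 95%). That value was also the commonest fold enrichment over all peaks, held by 1500 of them. Whether a low input sets the medians of this and the other gene lists was not tested. A low median was not particular to mitosis. Of 22 separate lists, 9 lay below the middle 95%, among them DNA replication, translation factors and splicing, 12 inside it and 1 above. Ranked by the best p instead, the mitotic genes stood at percentile 99.9, so fold enrichment and p placed them at opposite ends. Among peaks with at least the median fold enrichment of 5.02, the share of mitotic genes with a peak was 36.6% (percentile 90.9), inside the middle 95% of random lists. So were the shares of spindle and cytokinesis genes (percentile 82.3), kinetochore and checkpoint genes (94.96) and kinases, cyclins and their regulators (53.5), and the last list also with the top 10% of peaks by p (97.0) and without regions shared with another gene's peak (96.1). With the top 10% of peaks by p, the share of the joined mitosis lists was 22.3%, at percentile 100. A peak list does not tell which genes the cells express, so a share combines expression with enrichment. Nor was transcript length matched, for these or the other gene lists.

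**Figure D1:**
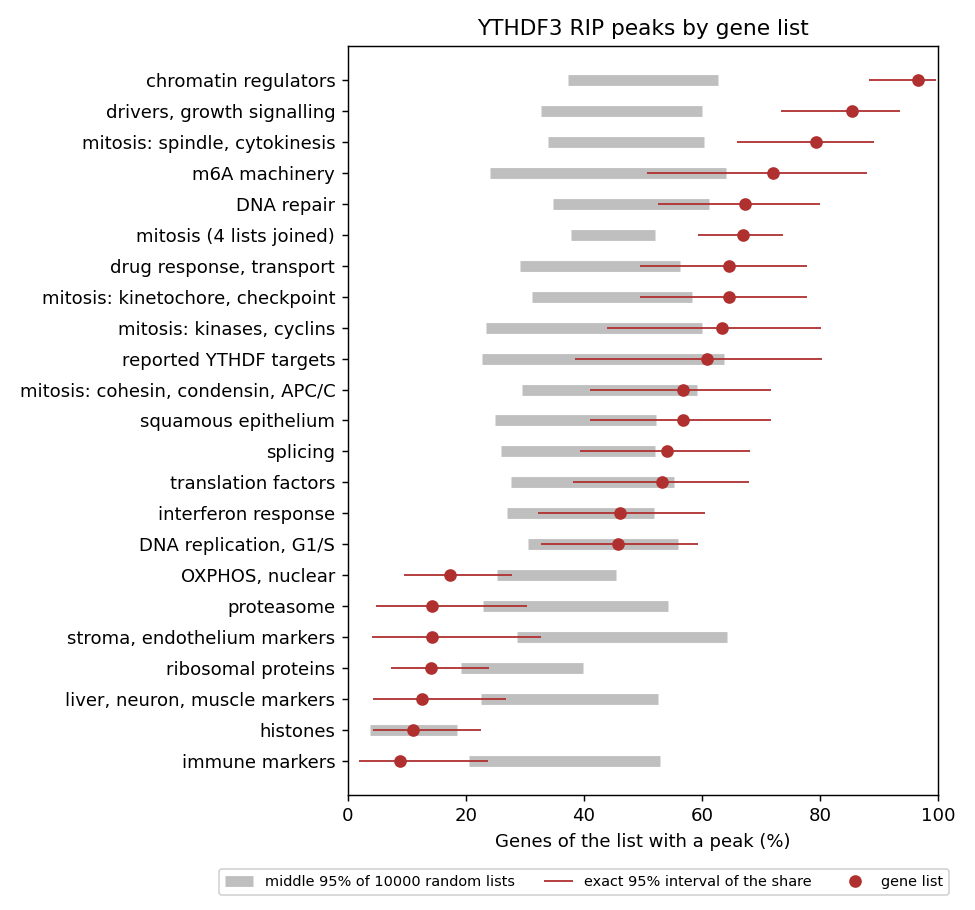
Share of the genes of each list with at least 1 YTHDF3 RIP peak in KYSE30 cells (points, percent of the list), with exact 95% intervals (thin lines) and the middle 95% of 10000 random lists of protein-coding genes matched on gene length (grey). Chromatin regulators lie highest at 96.6%, the 4 joined mitosis lists lie at 66.9%, and ribosomal protein genes lie at 14.1%, below their random lists.

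Chromatin regulators had a peak more often than any other list examined. Of 59 such genes, 57 had one (96.6%, percentile 100), and the exceptions were EED and HDAC1. ARID2 and ARID1A, both subunits of SWI/SNF remodelling complexes, had best fold enrichments of 47.7 and 31.4. The median over the list was 10.0, at percentile 98.9 among random lists, and it lay at percentile 38.1 when the median over each gene's peaks replaced its best peak. Matched on the number of peaks per gene, the best peaks lay at percentile 93.6.

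Genes altered in this cancer type and genes of growth signalling had a peak in 47 of 55 cases (85.5%, percentile 100). Their largest fold enrichments were in FAT2, an atypical cadherin, at 28.9 and in the ubiquitin ligase gene MDM2 at 28.4, the latter in a region that overlapped another gene's peak. Genes of this list without a listed peak included CTNNB1, NOTCH3, CUL3, ZNF750, AXIN2 and CDKN1A, named after their values were seen. Genes of drug response and drug transport had a peak in 31 of 48 cases (64.6%, percentile 99.9), led by the survival gene BCL2 at 26.3 and the death receptor gene TNFRSF10B at 21.3. That share lay inside the middle 95% of random lists with peaks of at least the median fold enrichment (percentile 57.8), with the top 10% of peaks by p (76.5) and without regions shared with another gene's peak (97.45). DNA repair genes had a peak in 33 of 49 cases (67.3%, percentile 99.6), with fold enrichments of 17.6 and 13.8 in the nucleotide excision repair genes ERCC4 and XPC, the XPC region overlapping another gene's peak.

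The m6A machinery had a peak in 18 of 25 genes (72.0%, 50.6 to 87.9), at percentile 99.7. The writer complex subunit ZC3H13 led with a fold enrichment of 43.4 on chromosome 13 from 45963847 to 46010266, and the methyltransferase METTL16 followed with 23.8. METTL14 had 4 peaks with fold enrichments of 15.1, 8.78, 3.55 and 2.15, the last with the smallest p. The catalytic subunit METTL3 had 1 peak with a fold enrichment of 5.02 and an adjusted p of 0.087, in a region that overlapped a peak of another gene. For YTHDF3 itself, the 2 peaks on chromosome 8 ran from 63168553 to 63211085 and from 63211294 to 63212786, the second with a fold enrichment of 5.02. With only peaks of at least the median fold enrichment, 48.0% of the machinery genes had a peak (percentile 95.4), inside the middle 95% of random lists. The share was also 48.0% with the top 10% of peaks by p, at percentile 100.

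Genes of ribosomal proteins, oxidative phosphorylation and the proteasome were at the other end. A peak was listed for 11 of 78 ribosomal protein genes (14.1%, 7.26 to 23.8), at percentile 0.075, and for 13 of 75 nuclear genes of oxidative phosphorylation (17.3%, 9.57 to 27.8), at percentile 0.020. Proteasome genes had a peak in 5 of 35 cases (14.3%, percentile 0.030, and 2.56 with the top 10% of peaks by p). RPL27A at 8.28 and RPL28 at 7.53 had the largest fold enrichments among ribosomal protein genes, NDUFB9 at 15.1 and ATP5MC3 at 11.3 among genes of oxidative phosphorylation, and PSMA7 at 7.53 and PSMD2 at 2.39 among proteasome genes. The NDUFB9 region overlapped a peak of another gene, and the adjusted p of the PSMA7 peak was 0.25. None of the 13 protein-coding genes of the mitochondrial genome had a listed peak, and the only mitochondrial peak lay in the ribosomal RNA gene MT-RNR2 from 2360 to 2660 with a fold enrichment of 2.89.

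Translation factors had a peak in 25 of 47 genes (53.2%, percentile 95.8). Their largest fold enrichment was 11.3 in EEF1D, and EIF4G1, EIF3B and EIF3F followed with 10.0 each. The adjusted p of the EIF3F peak was 0.078. The share lay above the middle 95% of random lists without regions shared with another gene's peak (98.7) and with the top 10% of peaks by p (97.6), and at percentile 3.32 with peaks of at least the median fold enrichment. Splicing genes had a peak in 27 of 50 cases (54.0%, percentile 98.3), with a best fold enrichment of 6.90 in PRPF8, a core spliceosome component. The median best fold enrichment of the splicing genes was 2.86, at percentile 0, and with only peaks of at least the median fold enrichment their share fell to percentile 0.17. DNA replication genes had a peak in 27 of 59 cases (45.8%, percentile 64.5), led by E2F2 at 66.5 and the cyclin gene CCNE1 at 11.3.

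**Figure D2:**
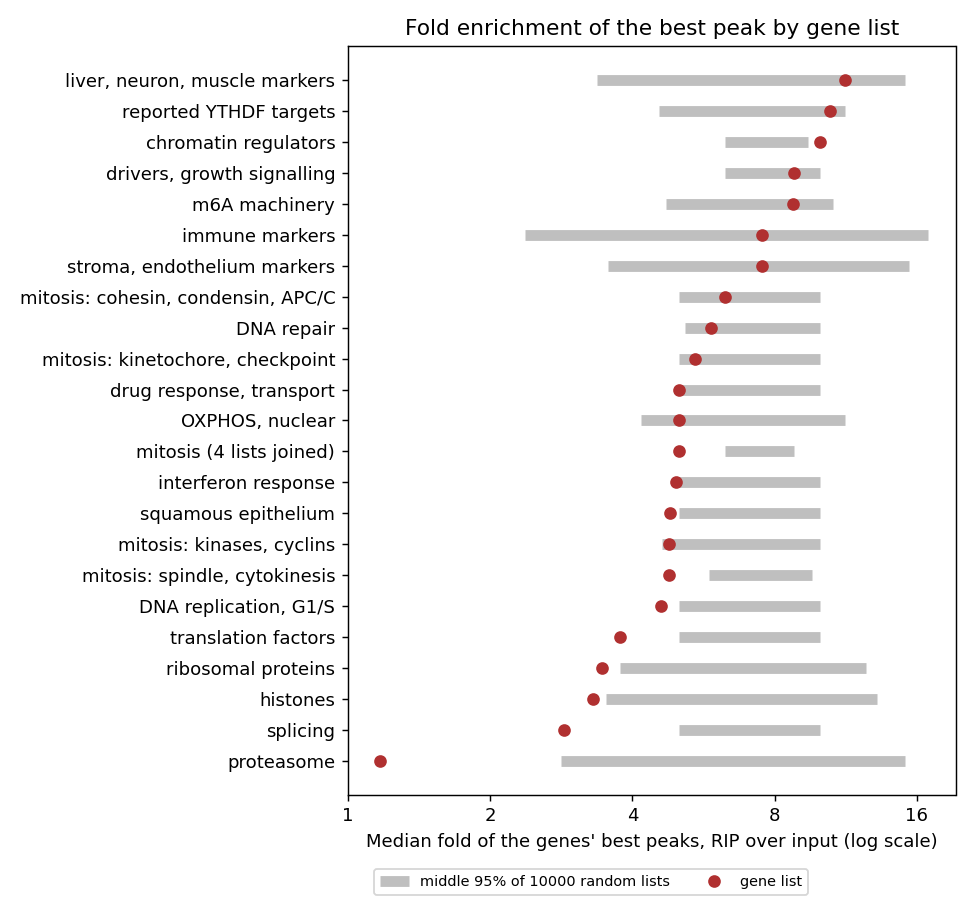
Median, over the genes of each list with a peak, of the fold enrichment of the best peak, RIP over input, on a log scale (points), with the middle 95% of 10000 random lists of genes with a peak matched on gene length (grey). Chromatin regulators lie above their random lists at 10.0, and the joined mitosis lists lie below theirs at 5.02. Many fold enrichments repeat the same values, and the input reads behind them are unknown.

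Squamous epithelium genes had a peak in 25 of 44 cases (56.8%, percentile 99.4), and with peaks of at least the median fold enrichment the share lay at percentile 46.4. Their largest fold enrichments were 22.8 in the epithelial transcription factor gene GRHL2 and 10.0 in the keratin gene KRT6B. Markers of other cell types served as a floor. Immune markers had a peak in 3 of 34 genes (8.82%, percentile 0.020), markers of stroma and endothelium in 4 of 28 (14.3%, percentile 0.020), and markers of liver, neurons and muscle in 5 of 40 (12.5%, percentile 0.020). CSF1R and CD14 had fold enrichments of 12.5 and 7.53, CDH5 and COL3A1 of 10.0 and 7.53, and MBP and SYT1 of 15.1 and 11.3, the MBP region overlapping another gene's peak. At an adjusted p under 0.05, 2, 0 and 4 genes of these 3 lists had a peak, against 107 of the 175 mitotic genes. With the top 10% of peaks by p, where few genes have a peak, the shares of these 3 lists lay inside the middle 95% of random lists, at percentiles 3.36, 3.70 and 10.9.

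Interferon response genes had a peak in 24 of 52 cases (46.2%, percentile 84.8), with DTX3L, in a region shared with another gene's peak, at 41.4 and IFIT3 at 11.9. Replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, had a peak in 6 of 54 cases (11.1%, percentile 64.8). The largest fold enrichments among these genes were 18.8 in H2AC11 and 3.76 in H2BC21, the latter with an adjusted p of 0.091. Their share lay below the middle 95% of random lists with peaks of at least the median fold enrichment (percentile 2.35) and with random lists not matched on length (percentile 0). Of 30 long noncoding RNA and related genes, 4 had a peak, among them TUG1 at 17.9 and SNHG7 at 15.1, both in regions shared with another gene's peak. Of 23 genes that earlier work on YTHDF proteins or m6A reported as targets, 14 had a peak (60.9%). Over the 22 of them in the background, the share was 63.6%, at percentile 96.9, and at 99.6 with peaks of at least the median fold enrichment. EP300, in a region shared with another gene's peak, had a fold enrichment of 25.1. Over the 22 separate lists that could be placed among random lists, 10 had a share above the middle 95%, 6 a share below it and 6 a share inside it. For the median best fold enrichment, 1 list lay above, 9 below and 12 inside.

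Short peaks lay mostly toward the 3' end of genes. Of 4105 peaks that spanned at most 1000 bases in genes longer than 10000 bases, 2500 (60.9%, 59.4 to 62.4) lay in the 10% of the gene nearest its 3' end and 530 (12.9%, 11.9 to 13.98) in the 10% nearest its 5' end. Of the 61 short peaks of mitotic genes, 38 (62.3%, 49.0 to 74.4) lay nearest the 3' end and 10 (16.4%, 8.15 to 28.1) nearest the 5' end. A different measure was taken over 17308 peaks of any span in genes found in the reference. Of these, 3000 (17.3%, 16.8 to 17.9) had a boundary within 100 bases of the gene's 5' end. A boundary within 100 bases of the 3' end was found for 2490 (14.4%, 13.9 to 14.9). A boundary does not locate the midpoint of a region, so these shares do not compare with those of short peaks. Position was measured along the genomic gene, introns included, and no random placement within exons was made.

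**Figure D3:**
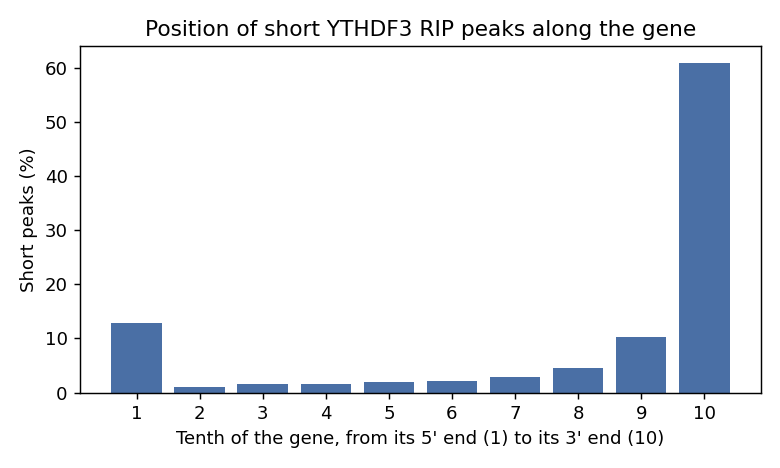
Share of 4105 short peaks (span of at most 1000 bases) by position of their midpoint along the gene, in 10 equal parts from the 5' end to the 3' end (bars, percent). The part nearest the 3' end holds 60.9% and the part nearest the 5' end 12.9%.

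The fold enrichments took few values. The 18466 peaks shared 826 distinct values, and the commonest, 7.53, was listed for 1500 peaks, 747 of them with the same p of 0.033. Across peaks, which are not independent replicates, fold enrichment and −log10 p had a rank correlation of 0.258.

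**Figure D4:**
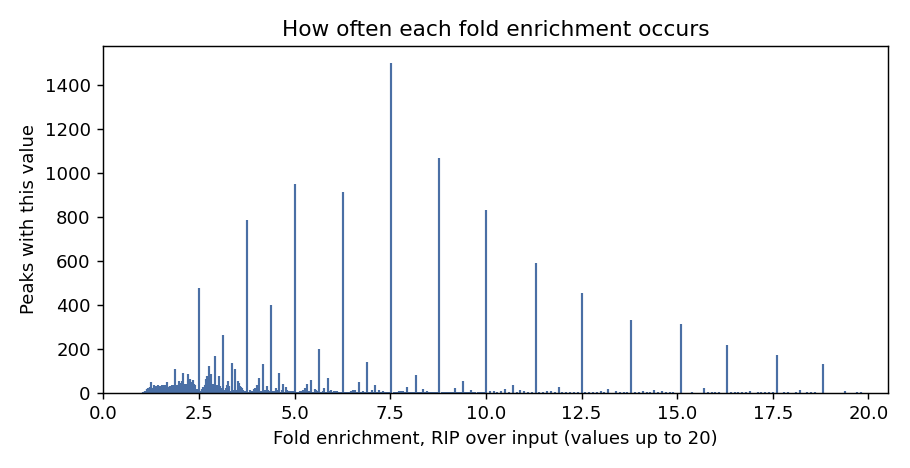
Number of peaks (vertical axis) with each listed fold enrichment, RIP over input (horizontal axis, values up to 20). Peaks pile up at evenly spaced values, the commonest being 7.53 with 1500 peaks.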

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

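The stricter adjusted p, the merging of peaks whatever the gene, the removal of regions shared with another gene, the top 10% by p for list shares, the background without genes that have no symbol of their own and the settings for short peaks were chosen after seeing the data. Over the results that answer the comparisons, 77 of the alternative values stayed on their side, 14 moved, 3 weakened, 1 strengthened and 3 reversed; the cause was not tested except where fewer peaks entered. Transcript parts, stop codons, motifs and a restriction to exonic peaks were not run, since sequence and transcript models were not used here, and no depth per library sets a limit that could be computed. No paired analysis was possible because each group has 1 library and no test was made.

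Keeping peaks of at least the median fold enrichment left 9863 peaks, and the top 10% by p left 1849 peaks in 1684 genes. At these 2 thresholds, the share of genes with a peak fell to 36.6% and 22.3% for the joined mitosis lists, 48.0% at both for the m6A machinery, 5.13% and 1.28% for ribosomal proteins, 9.33% and 0% for oxidative phosphorylation, and 78.0% and 40.7% for chromatin regulators. At the median fold enrichment the percentile of the share was 90.9 for mitosis and 95.4 for the m6A machinery. It fell from 98.3 to 0.17 for splicing, from 99.4 to 46.4 for squamous epithelium and from 64.8 to 2.35 for histones. Without matching on length, the histone share lay at percentile 0. With the top 10% by p, the percentile was 100 for mitosis, the m6A machinery and chromatin regulators. It was then 99.9 for squamous epithelium, 99.6 for splicing and 16.3 for histones.

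With p in place of fold enrichment, the percentile of the best peaks rose to 99.9 for the joined mitosis lists, 99.9 for spindle and cytokinesis, 98.9 for cohesin, condensin and the anaphase-promoting complex, 67.7 for DNA replication, 91.2 for translation factors, 65.8 for ribosomal proteins, 69.2 for the proteasome, 95.4 for splicing, 99.4 for squamous epithelium and 100 for the m6A machinery. For chromatin regulators it was 93.6 when matched on the number of peaks and 38.1 for the median over each gene's peaks. Naming the first 10 genes by p gave no value, since 144 genes share a p listed as 0. Short peaks of at most 500 bases lay in the 10% nearest the 3' end in 55.8% of cases.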

Other observations

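The comparison of gene families, the spacing of fold enrichments, the overlap of strands and the test of gene length for zinc finger genes were chosen only after the result was seen; for ribosomal protein, oxidative phosphorylation and zinc finger genes the raw shares or folds were known, but the percentiles that decide the other tests were not. Zinc finger genes of the ZNF series, mostly repressors that bind DNA, had a peak in 383 of 517 cases (74.1%, 70.1 to 77.8), against a median of 42.6% in random lists matched on gene length, at percentile 100. Their median best fold enrichment was 11.3, against 7.53 in random lists of genes with a peak, also at percentile 100. ZNF101 reached 47.7 on chromosome 19 from 19668796 to 19682193, and ZNF565 reached 41.4 on the same chromosome from 36182060 to 36213068. The related ZBTB genes had a peak in 38 of 42 cases (90.5%, percentile 100), with a median best fold enrichment of 11.3. The best fold enrichment was a multiple of the common step described for all peaks in 75.7% of the ZNF genes with a peak and in 63.7% of other protein-coding genes with one. Among the 93 ZNF genes whose best fold enrichment was not such a multiple, the median was 7.95, against 3.94 in random lists of such genes (3.14 to 4.39), at percentile 100. Values off the multiples also piled up, such as 4.39 with 398 peaks and 3.14 with 263, so a low input may set these too. This comparison therefore cannot tell whether a low input raises the fold enrichments of ZNF genes.

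Of 53 families of at least 30 protein-coding genes that share the letters of their symbol, 14 had a share of genes with a peak above the middle 95% of random lists and 17 a share below it. Centrosomal CEP genes (30 of 39, 76.9%), MED genes of the Mediator complex (22 of 30, 73.3%) and RNA-binding RBM genes (26 of 39, 66.7%) were among the former. Olfactory receptor genes (2 of 392, 0.51%), keratin genes (8 of 55, 14.5%) and collagen genes (8 of 44, 18.2%) were among the latter.

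Fold enrichments were evenly spaced: 50.3% of them were whole multiples of 1.2546 within the rounding of the list, 95.4 times the mean share for other steps. A candidate explanation is that in many peaks the fold enrichment comes from 1 window in which the input held 1 read or none, so that the fold counts RIP reads. The p of 2434 peaks (13.2%) equalled, within 0.011 on the log10 scale, the binomial value such a window would give, against a mean of 261 and at most 303 over 100 shuffles of p among the peaks on multiples. The bound on p set for this test was met by 100% of the peaks off the multiples too, so that part does not discriminate. Abundance in the input was not measured, and no biological explanation was tested.

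Peaks on opposite strands often coincided, in 1573 overlapping pairs. In the 112 pairs that overlapped by 80% or more, the log2 fold enrichments correlated across pairs with r = 0.928 (0.868 to 0.970, bootstrap), and 27.7% of pairs had identical fold enrichment and p, against r = 0.115 (0.087 to 0.143) and 0.52% in 4201 neighbouring pairs without overlap. This is consistent with the same reads counted for genes on both strands, although true transcription from both strands was not tested. Among protocadherin genes on chromosome 5, a single region ending at 141512979 with a fold enrichment of 6.90 was listed for 21 genes.

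The low share of ribosomal protein and oxidative phosphorylation genes with a peak is not accounted for by short genomic length alone. Among random lists matched on that length, the higher of the 2 percentiles was 0.075. Transcript length was not matched, so short transcripts were not tested as an explanation. Reads shared with processed pseudogenes stay open: of the 75 oxidative phosphorylation genes, 26 have no pseudogene of their name in the reference, and 6 of these had a peak (23.1%, 8.97 to 43.6), at percentile 12.01, an interval that holds both the share of the whole list and that of random lists. For ribosomal proteins, 0 genes were without such a pseudogene, so that test could not be made. Abundant transcripts with few m6A sites are a biological explanation that was not tested, and high input levels may likewise keep a fold enrichment low.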
